A study of Homo sapiens with 3 samples.

How the data were processed

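The 3′ ends of the human telomerase RNA (hTR) were sequenced from 3 immunoprecipitates, with 1 library for each of the proteins PABPN1, hTERT and DKC1. Per the labels' protocols, each protein carried a FLAG tag and was expressed in HEK293-derived human embryonic kidney cells from a tetracycline-sensitive promoter induced with doxycycline at 500 ng/ml. RNA bound to the protein was recovered with an anti-FLAG antibody. An oligonucleotide was then ligated to the 3′ ends, hTR was amplified by reverse transcription and 3 successive rounds of PCR with a barcode per sample, and the libraries were sequenced on a MiSeq instrument, per the labels' protocols. A ligated linker marks the 3′ end of each molecule that received it, so nucleotides added at that end can be read.

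Each deposited table held whole-number read counts, 1 row per length of genomic addition from 0 to 199 nt and 1 column per polyadenylation length, per the file headers. The 6 columns were headed 0, 2, 3, 4, 5 and 6, and no column was headed 1. How a single added adenosine was counted, whether the last column also held longer tails, how adenosines were told from genome-encoded ones and whether duplicate reads were removed were not given in the sources used here. cutadapt, Bowtie, Bowtie2 and build hg38 are named in the submitters' processing notes, with no role or order. An addition of 0 nt was taken here as the mature 3′ end, which the headers do not define. The tables list no ends short of it, so the planned share of shortened ends was not computed, and every share refers to reads that reach the mature end or pass it. "Tailed" means a polyadenylation length of 2 or more.

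The counts were used as deposited, with no normalization, and each library was described by shares of its own reads. Depth was 2658507 reads for PABPN1, 3040560 for hTERT and 2996292 for DKC1. Shares have 95% exact Clopper-Pearson intervals, whose bounds lie within 0.0601 points of any share of all reads in a library. A difference between libraries has a Newcombe interval in percentage points, a ratio has a Katz log interval, and a ratio at matched length has a log-normal one from the binomial variances. As an approximate one-sided limit of 3 reads, a count of 0 would allow a share of up to 9.87e-05% in the deepest library and 0.000113% in the shallowest; the exact interval for 0 reads is wider, up to 0.000121% and 0.000139%. PCR reads without molecular identifiers are not independent molecules, so every interval and floor covers counting error only. With 1 library per protein there is no replicate error, and no test between proteins was made. No input RNA and no mock precipitate were analysed here, so no background could be set beside the values.

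End profiles were compared by total variation distance, the share of reads that would have to change position to turn a profile into another. Its counting error was taken from 200 simulated pairs of libraries. Tailed shares at matched addition length were averaged over the addition lengths holding at least 10 reads in both libraries, weighted by the mean of both profiles. The rule for named positions, fixed before the data were examined, took the mature end, the 3 additions and 3 tail lengths with the largest share in each library, and the 3 additions with the largest difference between libraries in each direction. The classes of addition length, the matched comparison, the cutoffs of 15, 20 and 40 nt and the removal of possibly misassigned reads were chosen after seeing the data. On 200 simulated pairs of libraries drawn from the PABPN1 and hTERT profiles over 200 addition lengths, the intervals held the true value in 94% (Clopper-Pearson), 95% (Newcombe), 95.5% (Katz) and 95.5% (matched ratio) of pairs. The simulated reads were drawn independently, so this checks the formulas and not the coverage for PCR reads. Alternatives were a wider mature end, a minimum of 10 reads per addition, leaving out the most abundant addition, longer cutoffs for extension and tail, and bins of 5 nt. For that removal, each class of addition length lost as many reads, tailed and untailed, as the level from 40 nt on gives per PABPN1 read. The level was taken as exact, and it treats every hTERT and DKC1 read from 40 nt on as misassigned, an extreme case. Positions next to a genome-encoded adenosine could not be left out, because no genome sequence was used here. The hTR gene (TERC, gene ID 7012) was located with the RefSeq gene table of GRCh38.p14, the assembly to which hg38 corresponds. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.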

Results

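The 3′ ends of hTR were compared between RNA bound to 3 proteins. hTR is the template RNA of telomerase and is encoded by TERC, which spans positions 169764610 to 169765060 of chromosome 3 in GRCh38.p14 and is annotated there as telomerase RNA. With an addition of 0 nt taken as the mature end, the genome-encoded additions lie downstream of this annotated gene. PABPN1 is the nuclear poly(A)-binding protein, hTERT is the reverse transcriptase of telomerase, and DKC1 (dyskerin) is a protein of the H/ACA ribonucleoprotein that holds mature hTR. The series asked which polyadenylated forms of hTR exist, and the design sets RNA bound by the poly(A)-binding protein against RNA bound by these telomerase proteins. Each protein has 1 library, of 2658507 reads for PABPN1, 3040560 for hTERT and 2996292 for DKC1. All values below are read counts as deposited or shares of them, with intervals for counting error only.

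The mature 3′ end was the most frequent end in all 3 libraries, and the remaining reads carried genome-encoded nucleotides past it. Mature ends made up 48.1% of PABPN1 reads, 46.0% of hTERT reads and 44.2% of DKC1 reads. Ends extended by 1 nt or more were the complement, at 51.9%, 54.0% and 55.8%. The PABPN1 library thus held 2.09 points more mature ends than the hTERT library (95% interval 2.01 to 2.18) and 3.89 points more than the DKC1 library (3.81 to 3.97), while the hTERT library held 1.80 points more than the DKC1 library (1.72 to 1.88). These differences exceeded counting error, but no replicate libraries show how far a repeat would move them. They also depended on the exact boundary: with the mature end widened by 2 nt the shares were 58.8%, 58.1% and 58.3%, so PABPN1 was 0.66 points above hTERT and 0.47 above DKC1, and hTERT was 0.191 points below DKC1. Later cutoffs for extension changed the order of the libraries too, as the next comparison shows.

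Long extensions were more frequent in the PABPN1 library than in the others. Ends extended by 10 nt or more made up 21.7% of PABPN1 reads, against 3.47% in hTERT and 2.98% in DKC1, a ratio of 6.26 (95% interval 6.22 to 6.30) and 7.29 (7.24 to 7.34). The ratio was larger at later cutoffs up to 40 nt. From 15 nt on, the shares were 15.2%, 0.636% and 0.529%, or 23.9 times (23.6 to 24.2) the hTERT share and 28.7 times (28.3 to 29.2) the DKC1 share. From 20 nt on they were 7.53%, 0.194% and 0.163%, or 38.8 times (37.8 to 39.8) and 46.1 times (44.8 to 47.4). From 40 nt on, with only 216 hTERT and 149 DKC1 reads, the ratios were 74.4 (65.0 to 85.1) and 106 (90.4 to 125). The ratios at long additions depend on whether PABPN1 reads were counted in the wrong library. Without reads at the level seen from 40 nt on, the ratios from 20 nt on would be 81.1 and 81.4. These values mark an extreme case, because the removal takes every hTERT and DKC1 read from 40 nt on as misassigned, which was not shown. Ends extended by 50 nt or more were counted in 5061 PABPN1 reads, 72 hTERT reads and 54 DKC1 reads. The longest addition with a read was 189 nt in PABPN1, 163 nt in hTERT and 120 nt in DKC1, and beyond 99 nt there were 110, 2 and 1 reads.

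Among extended ends, the median addition was 8 nt in PABPN1 (quartiles 3 and 16) and 5 nt in both hTERT (3 and 7) and DKC1 (2 and 7). The hTERT and DKC1 libraries had a hump of ends centred on an addition of 6 nt, which took 8.26% and 8.00% of their reads, against 3.19% of PABPN1 reads. PABPN1 had a lower hump in the same range, with a local maximum at 5 nt. An addition of 5 nt took 7.83% of hTERT, 7.92% of DKC1 and 3.19% of PABPN1 reads. These were the additions with the greatest deficit in PABPN1, at 5.07 points below hTERT for 6 nt (95% interval of PABPN1 minus hTERT -5.10 to -5.03) and 4.63 points for 5 nt (-4.67 to -4.60). The next were 7 nt against hTERT and 4 nt against DKC1. An addition of 7 nt took 3.08% of PABPN1, 6.30% of hTERT and 6.05% of DKC1 reads, and 4 nt took 2.15%, 5.005% and 5.47%. In PABPN1 a further local maximum lay at 17 nt, with 1.64% of reads, where hTERT had 0.0823% and DKC1 0.0681%. After the mature end, 17 and 16 nt were the additions with the greatest excess in PABPN1, by 1.56 points (1.54 to 1.57) and 1.49 points (1.47 to 1.50) over hTERT and by 1.57 and 1.51 points over DKC1. An addition of 16 nt took 1.59% of PABPN1, 0.103% of hTERT and 0.0828% of DKC1 reads.

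**Figure D1:**
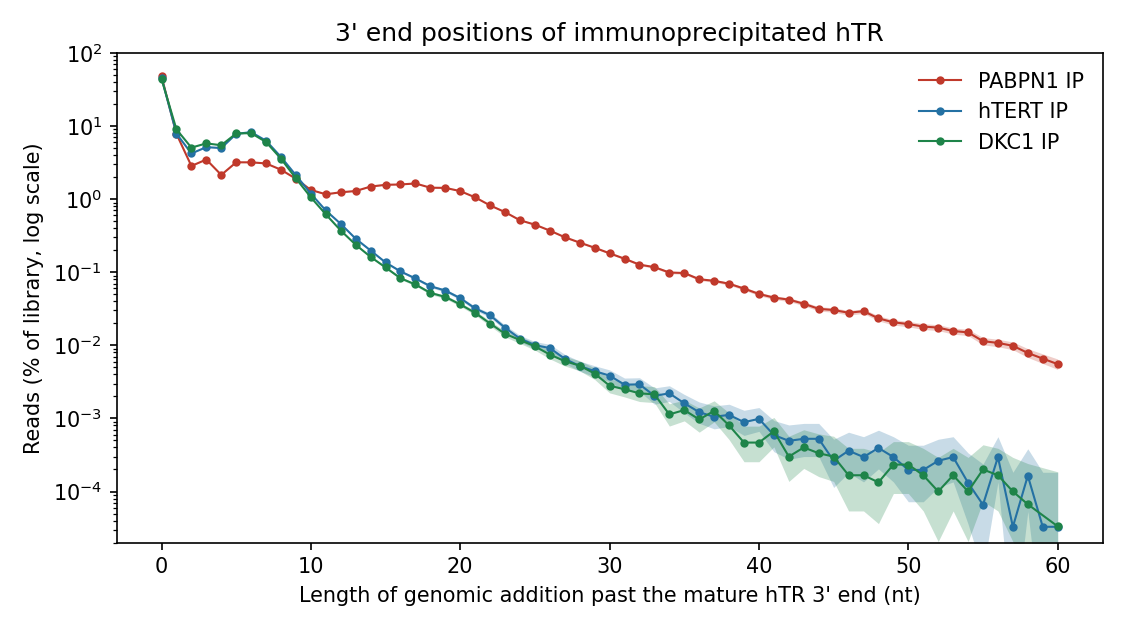
Share of each library's reads (%, log axis) ending at each length of genomic addition past the mature hTR 3′ end (nt, 0 to 60; additions with no read are left out). Points are single libraries and bands are 95% exact binomial intervals. The PABPN1 line lies below the others at 1 to 9 nt and above them from 10 nt on. At 17 nt it has 1.64% of reads against 0.0823% in hTERT and 0.0681% in DKC1.

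The hTERT and DKC1 profiles were close to each other and apart from that of PABPN1. The total variation distance was 3.20% of reads (95% interval 3.13 to 3.27) between hTERT and DKC1, 20.3% (20.3 to 20.4) between PABPN1 and hTERT, and 22.6% (22.5 to 22.7) between PABPN1 and DKC1. Counting error alone gave at most 0.17% in the simulated hTERT and DKC1 pairs, so these libraries also differed from each other by more than counting error. Their largest difference was the 1.80 points at the mature end itself, followed by the additions next to it. Additions of 1, 2 and 3 nt took 9.02%, 5.07% and 5.80% of DKC1 reads, against 7.89%, 4.22% and 5.15% of hTERT reads, and the respective PABPN1 shares were 7.83%, 2.85% and 3.49%. After the mature end, the largest excesses of hTERT over DKC1 were 0.254 points (0.210 to 0.297) at 6 nt and 0.2499 points (0.212 to 0.288) at 7 nt.

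Adenosine-tailed hTR was found with all 3 proteins and was more frequent with PABPN1. Tails of 2 or more adenosines were carried by 8.21% of PABPN1 reads (95% exact interval 8.18 to 8.24), 3.80% of hTERT reads (3.78 to 3.82) and 3.70% of DKC1 reads (3.67 to 3.72). PABPN1 therefore had 2.16 times the hTERT share (2.15 to 2.18) and 2.22 times the DKC1 share (2.21 to 2.24), while hTERT and DKC1 differed by 0.102 points (0.0719 to 0.133). With only tails of 5 or more adenosines, the shares were closer in proportion, at 0.387%, 0.276% and 0.232%. Tails lay almost entirely on extended ends, which made up 98.4% of tailed reads in PABPN1, 97.4% in hTERT and 97.6% in DKC1. Of mature ends, 0.273%, 0.215% and 0.202% were tailed. Of extended ends, 15.6%, 6.85% and 6.46% were tailed. The median addition beneath a tail was 12 nt in PABPN1, against 7 nt for its untailed extended ends, whereas in hTERT and DKC1 it was 4 nt beneath a tail and 5 nt without.

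The listed tails were short. Tails of 2 adenosines formed 65.4% of tailed reads in PABPN1, 58.0% in hTERT and 57.8% in DKC1. Tails of 3 formed 20.2%, 22.1% and 24.02%, and tails of 4 formed 9.65%, 12.7% and 11.9%. As shares of all reads, every listed tail length was more frequent in PABPN1, from 5.37% against 2.20% and 2.13% for 2 adenosines to 0.227% against 0.177% and 0.149% for 6. The median tail was 2 adenosines in each library. At the mature end, where only 3485, 2999 and 2671 reads were tailed, the leading tail length was 3 adenosines, with 56.8%, 50.8% and 55.4% of the tailed mature ends (a feature singled out after its values were seen). Tails of 1 adenosine have no column in these tables, and the last column may or may not hold tails longer than 6.

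In all 3 libraries the tailed share was higher in each class of additions from 10 to 69 nt than in the class of 5 to 9 nt. For additions of 1 to 4 nt, 15.3% of PABPN1 ends, 9.18% of hTERT ends and 8.01% of DKC1 ends were tailed, but this class was carried by the addition of 3 nt, without which the shares were 8.31%, 5.56% and 5.34%. For additions of 5 to 9 nt, 7.66% of PABPN1 ends, 4.65% of hTERT ends and 4.75% of DKC1 ends were tailed. At 10 to 14 nt the shares were 14.8%, 7.58% and 7.24%, and at 15 to 19 nt 16.6%, 16.0% and 14.4%. At 20 to 24 nt they were 22.0%, 22.9% and 19.6%, and at 25 to 29 nt 35.4%, 29.9% and 28.5%. At 30 to 39 nt they were 44.6%, 41.2% and 46.5%. Depth limits the last of these outside PABPN1. The class held 28237 PABPN1 reads, 602 hTERT reads and 467 DKC1 reads. Its intervals ran from 37.2 to 45.2% in hTERT and from 41.9 to 51.1% in DKC1. Possibly misassigned PABPN1 reads are a further limit. At the level seen from 40 nt on, an extreme case, they would be 60.4% of hTERT and 45.9% of DKC1 reads at 25 to 29 nt. At 30 to 39 nt they would be 72.1% and 64.1%. Without them, the hTERT share was 23.6% at 20 to 24 nt (interval 21.3 to 26.0). At 25 to 29 nt it was 21.5% (14.6 to 28.4). These intervals overlap and take the level as exact, so a rise of the hTERT share there was neither shown nor excluded. With the same removal, the DKC1 shares were 18.2% (16.1 to 20.4) and 22.6% (17.3 to 27.8), whose intervals also overlap.

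The higher tailed share of PABPN1 was therefore not spread evenly over addition lengths. At matched additions of 1 to 14 nt, PABPN1 had 1.72 times the tailed share of hTERT (95% interval 1.71 to 1.74) and 1.86 times that of DKC1 (1.84 to 1.87). At matched additions of 15 nt or more the ratio was 1.02 over hTERT (0.989 to 1.05), which includes equality, and 1.11 over DKC1 (1.07 to 1.15). Single classes within this range went both ways. At 25 to 29 nt PABPN1 was 5.50 points above hTERT (2.67 to 8.20), and at 50 to 69 nt, with 62 hTERT reads, hTERT had 79.0% tailed ends and PABPN1 57.0%; at 40 to 49 nt, with 95 DKC1 reads, PABPN1 was 11.4 points below DKC1 (-20.4 to -1.35). The near-equality with hTERT also depended on whether some of these few reads were PABPN1 reads counted in the wrong library. At 15 to 29 nt, leaving out reads at the level seen from 40 nt on moved the ratio from 1.03 to 1.07 (1.01 to 1.13) over hTERT. Over DKC1 it moved from 1.16 to 1.25 (1.18 to 1.32). The hTERT shift came mostly from 25 to 29 nt, where the hTERT share went from 29.9% to 21.5%. At 20 to 24 nt it went from 22.9% to 23.6%, against 22.0% in PABPN1. These intervals take the level as exact, although for hTERT it ran from 1.34 to 1.76 per 100 PABPN1 reads. The ratio of hTERT over DKC1 was 1.07 (1.06 to 1.08) for short additions and 1.10 (1.05 to 1.15) for long ones. Over all additions past the mature end, matching lowered the ratio of PABPN1 over hTERT from 2.27 to 1.47 and that over DKC1 from 2.41 to 1.59. How far it was lowered depended on the weights, since the ratio differed by length. With the weights of the second library the matched ratios were 1.71 and 1.85.

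**Figure D2:**
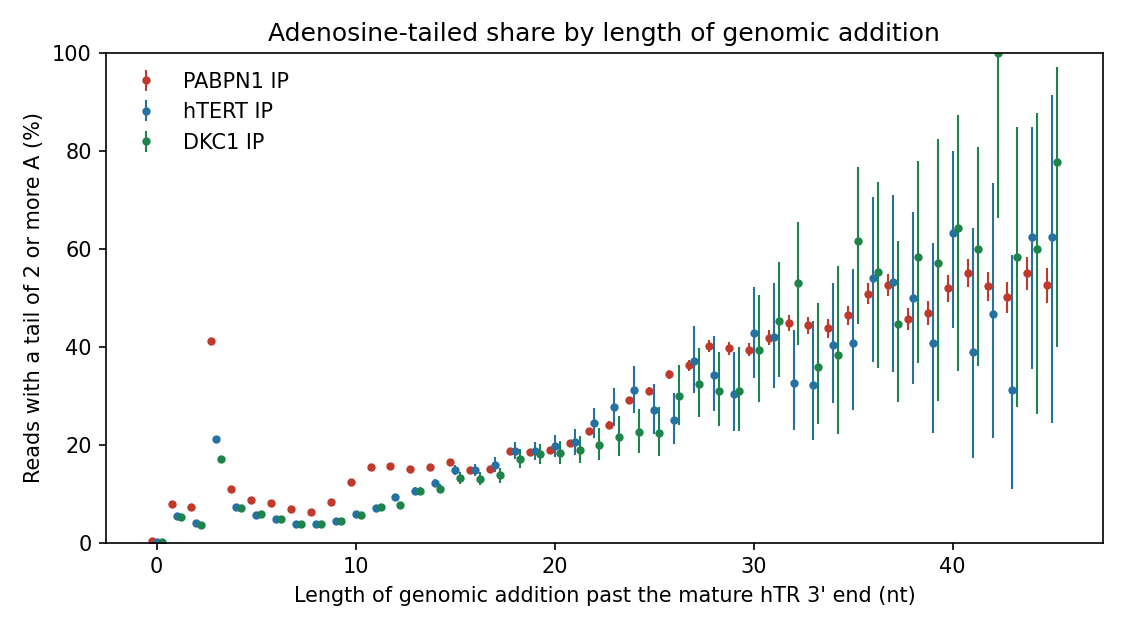
Share of reads with a tail of 2 or more adenosines (%) at each length of genomic addition (nt, 0 to 45) in the 3 libraries. Points are single libraries, drawn slightly apart, and bars are 95% exact binomial intervals; PABPN1 lies above hTERT and DKC1 from 1 to 14 nt, while at 15 to 19 nt the classes come to 16.6%, 16.0% and 14.4%.

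Near the mature end, tails were most frequent at an addition of 3 nt. At an addition of 3 nt, 41.3% of PABPN1 ends, 21.2% of hTERT ends and 17.0% of DKC1 ends were tailed, mostly with 2 adenosines. For every 100 untailed reads at 3 nt there were 64.5 reads with 2 adenosines in PABPN1 (95% interval 63.6 to 65.4), 22.5 in hTERT (22.3 to 22.8) and 16.6 in DKC1 (16.4 to 16.8). At 2 nt the values were 3.87, 1.43 and 1.29, and at 4 nt 5.61, 2.35 and 2.45. At 1 nt they were 6.12, 3.38 and 3.67, above the values at 4 nt but far below those at 3 nt. The tails of 2 adenosines at 1 and 3 nt together made up 21.5% of all tailed reads in PABPN1, 30.7% in hTERT and 30.1% in DKC1. Without them, tailed reads came to 6.56%, 2.66% and 2.61%, so PABPN1 remained above both other libraries.

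**Figure D3:**
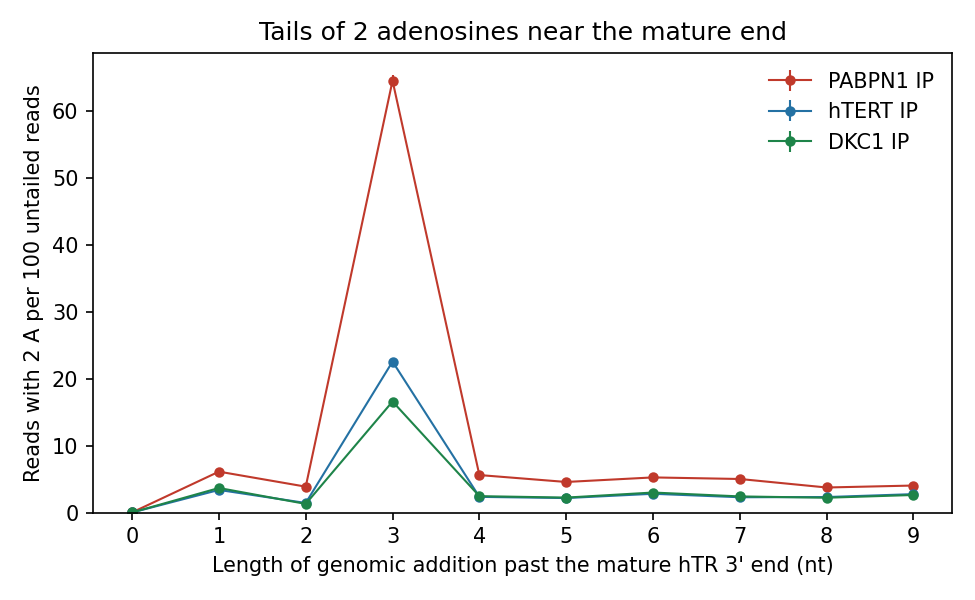
Reads with a tail of 2 adenosines per 100 untailed reads (linear axis) at additions of 0 to 9 nt in the 3 libraries, with 95% counting intervals as bars, many of them smaller than the points. All 3 libraries peak at 3 nt, at 64.5 in PABPN1, 22.5 in hTERT and 16.6 in DKC1.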

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

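The PABPN1 excess of tailed ends kept its direction in each alternative that could change it. The order of the libraries in extended ends depended on where extension begins. Of 104 alternative values, 31 stayed within the counting interval of the reported value, 60 moved outside it and 13 changed sign. The intervals are so narrow that small shifts count as moved. Some of the 31 could not move: widening the mature end, or a minimum of 2 adenosines, leaves tailed shares unchanged by construction. Libraries are named in the order PABPN1, hTERT, DKC1. With the mature end widened by 1 nt, mature shares were 55.9%, 53.9% and 53.2%, and extended shares 44.1%, 46.1% and 46.8%; widened by 2 nt they were 58.8%, 58.1% and 58.3%, and 41.2%, 41.9% and 41.7%. The most abundant addition past the mature end was 1 nt in PABPN1 and DKC1 and 6 nt in hTERT. Without it, mature shares were 52.2%, 50.1% and 48.6%, and extended shares 47.8%, 49.9% and 51.4%. Extended shares were 35.6%, 31.8% and 30.5% from 5 nt on and 21.7%, 3.47% and 2.98% from 10 nt on. Differences in extended share are given in points as PABPN1 minus hTERT, PABPN1 minus DKC1 and hTERT minus DKC1. They were -2.03, -2.69 and -0.66 with 1 nt of width and -0.66, -0.47 and 0.191 with 2 nt. They turned positive with longer cutoffs, added after seeing the data, at 3.86, 5.16 and 1.30 from 5 nt on, 18.3, 18.7 and 0.49 from 10 nt, 14.6, 14.7 and 0.107 from 15 nt, and 7.34, 7.37 and 0.0307 from 20 nt. This follows from the construction, since PABPN1 had fewer ends at 1 to 9 nt than the others and hTERT fewer at 1 to 4 nt than DKC1. Tails of 5 or more adenosines left 0.387%, 0.276% and 0.232% of reads, and a minimum of 2 equals the reported definition. Without tails of 2 at additions of 1 and 3 nt, also added later, tailed shares were 6.56%, 2.66% and 2.61%, their differences 3.90, 3.95 and 0.049 points, and the matched ratios 1.33, 1.40 and 1.03. Weights of the second library gave matched ratios of 1.71 and 1.85 for PABPN1, and bins of 5 nt gave 1.49 over hTERT. At 15 to 29 nt, leaving out reads at the level seen from 40 nt on, added later, moved the ratio of PABPN1 from 1.03 to 1.07 over hTERT and from 1.16 to 1.25 over DKC1. The same removal gave ratios of the share extended from 10, 15 and 20 nt on of 6.84, 35.2 and 81.1 over hTERT and 7.83, 39.4 and 81.4 over DKC1, in place of 6.26, 23.9 and 38.8 and of 7.29, 28.7 and 46.1. From 5 nt on, median additions were 13, 6 and 6 nt. Profile distances in the same pair order were 18.3%, 18.7% and 1.30% in bins of 5 nt and 35.9%, 36.7% and 4.23% without the mature end. Leaving out additions under 10 reads changed no value beyond its interval. Shares short of the mature end and the filter on genome-encoded adenosines were not run. No paired analysis was possible because each group has 1 library. Depth limits the tailed shares from 40 nt on, which rest on 216 hTERT and 149 DKC1 reads.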

Other observations

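All explanations and tests in this part were chosen after the counts had been seen. With 1 library per protein, none of them separates a difference between proteins from a difference between libraries.

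The excess of tailed ends in PABPN1 was larger at additions under 15 nt than from 15 nt on, where the matched ratio over hTERT was 1.02 (95% counting interval 0.989 to 1.05), or, for 15 to 29 nt without reads at the level of possible misassignment, 1.07 (1.01 to 1.13). A bias towards longer amplified products in the PABPN1 library would act on the addition and the tail together, so at matched total added length (2 to 14 nt) it predicts equal tailed shares. The observed ratio of PABPN1 over hTERT was 1.58 (95% counting interval 1.57 to 1.59), which argues against that bias as the whole source. Variation between single libraries stays open, since the ratio of hTERT over DKC1 for additions of 1 to 14 nt, 1.07, is far smaller than the 1.72 of PABPN1 over hTERT but compares different proteins and does not measure the spread of repeats. A preference of PABPN1 for tailed or for incompletely trimmed hTR also stays open and was not tested.

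The few long ends in the hTERT and DKC1 libraries may in part be PABPN1 reads assigned to the wrong barcode, if the libraries shared a sequencing run, and these would stand in a fixed proportion to PABPN1 reads at every length. hTERT reads per 100 PABPN1 reads fell from 6.59 at 15 to 19 nt to 1.54 from 40 nt on, and the level at 15 to 29 nt was 3.33 times that from 40 nt on (95% interval 2.91 to 3.81). Misassignment therefore cannot be the whole source of the additions of 15 to 29 nt in hTERT, but at the level seen from 40 nt on it would make up 30.03% of them, from 23.3% at 15 to 19 nt to 60.4% at 25 to 29 nt, and 72.1% at 30 to 39 nt. From 40 nt on, the level at 40 to 59 nt over that at longer additions was 1.15 in hTERT (0.728 to 1.80) and 1.10 in DKC1 (0.645 to 1.88), within wide intervals that misassignment predicts to include 1, while the tailed share was 8.23 points above that of PABPN1 in hTERT (1.55 to 14.5) and 5.26 points above in DKC1 (-2.81 to 12.9). By counting error alone, this difference in tailed share excluded equality in hTERT and not in DKC1. Such intervals may be too narrow for PCR reads, so misassigned reads alone stay open from 40 nt on in both libraries. Each library departed from PABPN1 in 1 part of the range. The hTERT difference was 19.4 points from 50 nt on (8.22 to 28.1, 72 reads) against 2.76 at 40 to 49 nt (-5.46 to 10.7). The DKC1 difference was 11.4 points at 40 to 49 nt (1.35 to 20.4, 95 reads) against -5.60 from 50 nt on (-18.6 to 7.36).

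The peak of 2-adenosine tails at an addition of 3 nt was seen in 3 of 3 libraries among additions of 0 to 9 nt. In the hTERT library it was 11.9 times the mean of the values at 2 and 4 nt (95% interval 11.6 to 12.3), which argues against selection by PABPN1 alone. Both values restate the peak that prompted the question, so they are no separate support for a cause. A feature of this position common to all libraries would give both. It could be a preferred site of adenosine addition or of stalled trimming, or a place where genome-encoded adenosines are counted as added; no genome sequence was used here, so these were not separated.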
